A study of Homo sapiens with 10 samples.

How the data were processed

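H3K9ac, histone H3 acetylated at lysine 9, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 4 kinds of HEK293T cells: the parental line, a METTL3 knockout (KO), and the KO complemented with wild-type METTL3 or with METTL3 D395A, which the labels describe as catalytically inactive. The series holds 10 libraries, 8 of them ChIP libraries (2 per kind of cell) and 2 of them inputs (1 of HEK293T and 1 of the KO). Cells were crosslinked with 1% formaldehyde for 10 min, per the labels' protocols.

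Per the submitters' processing notes, the tools included Bowtie2 2.4.5, Picard 2.27.3, SAMtools 1.15.1, MACS2 2.2.7.1, bedtools 2.30.0, deepTools 3.5.1 and HOMER 4.8.2, and the genome build was hg38. The notes used here give no roles or settings for these tools. The authors deposited 4 peak lists in the broad-peak layout, 1 per kind of cell, so the ChIP replicates do not appear as separate lists. How the replicates were combined, which input served as control and how the caller was set are not given in the sources used here. Each peak carries a fold enrichment, the ratio of ChIP to background as deposited by the authors, with its −log10 q from the peak caller, and a score that the authors' lists set to 10 times the −log10 q, rounded down, in 99.8% to 99.9% of the peaks of each list. The −log10 p columns of the deposited lists, 4 in all, were not used. The smallest deposited −log10 q was close to 1 in every list. These values are the authors' own. They served mainly to describe, rank or filter peaks within a list, because background and depth can differ between lists. Where the text sets such values, or counts based on them, side by side between lists, the comparison is descriptive. A limit on −log10 q applied to every list carries the same uncertainty. The peak lists hold no read counts, so the depth of each library is unknown here, and a list from deeper or cleaner libraries can hold more weak peaks with no change in the cells.

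Peak lists were compared by overlap of at least 1 base. A peak is called missing from another list when no peak of that list overlaps it. Shares carry 95% Wilson intervals, which cover counting error only. Peaks and genes of 1 list are not replicates, so no p-value was computed and a difference between lists has no replicate check. Chance overlap was measured by shifting one list around each chromosome 100 times. Covered bases were compared with the Jaccard index, the bases shared by both lists divided by the bases covered by either. Strong peaks are those with −log10 q of at least 20 in the list where they are present; that limit was chosen after the data were examined.

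Genes came from a RefSeq table of assembly GRCh38.p14, whose primary chromosomes share their coordinates with hg38; 19974 protein-coding genes on chromosomes 1 to 22 and X were used. The table gives gene spans without strand, exons or transcript starts. The planned window around transcription start sites was therefore replaced by a window of 1 kb on each side of either end of the gene, and a gene was scored as having a peak when a peak overlapped that window. A peak at the 3′ end counts the same as a peak at the 5′ end, and exonic and intronic positions are not told apart. Covered bases of a gene were counted within 5 kb on each side of the gene end with more bases covered over the 4 lists together, a window of 10001 bp. A gene that lacks a peak by the 1 kb rule can still lie beside a wide peak, so the text gives covered bases for many such calls; a call without them says only that no peak lay within 1 kb of a gene end. A difference is called one of peak borders where the scoring peak itself overlaps a peak of the other list, a check added after the data were examined.

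Genes are named by a rule set before the data were examined: the 10 genes with the highest HEK293T fold enrichment among those with a peak in HEK293T and none in KO; the 10 with the highest KO fold enrichment among the opposite set; the 5 largest decreases and 5 largest increases of covered bases among genes with a peak in both; up to 10 genes regained in 1 rescue list only, for each rescue; METTL3, METTL14, HAT1, RBBP7 and any m6A or acetyltransferase gene whose status differed between lists; and up to 4 members of each of 26 gene lists. Among the ranked genes, those sharing a peak are named together. Members of the gene lists can share a peak and be named apart. Other genes are named where the text says that they were chosen after their values were seen. The 26 lists covered m6A factors, histone acetyltransferases, deacetylases, histone genes, ribosomal proteins, proteasome, respiratory chain, DNA replication, DNA repair, immediate early, interferon, unfolded protein, cholesterol, p53, signalling targets, epithelial-mesenchymal, kidney, neuronal, HOX, pluripotency and germline, haematopoietic, hepatocyte, zinc finger, protocadherin, olfactory receptor and chromatin remodeller genes. Each list was compared with 10000 random gene lists of the same size. These were matched on deciles of HEK293T fold enrichment for the number of genes without a KO peak. For the change of coverage they were matched on deciles of HEK293T covered bases. For genes with a KO peak and no HEK293T peak, random lists were drawn from genes without a HEK293T peak. Over all quantities, 152 such comparisons were made, and a percentile describes these 4 lists and is not a p-value. Neighbouring genes of a cluster share peaks, which random lists of scattered genes do not.

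The alternatives set in advance were a minimum −log10 q of 5 in every list, lists cut to equal length, a minimum −log10 q of 5 only where a peak is present, chromosomes 1 to 22 and X only, 50% of a peak covered, merging within 1000 bp, gene windows of 500 and 2500 bp, 1 end per gene, and random lists matched on size alone. Absence within 5000 bp and the limit for strong peaks were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the computing, and matplotlib 3.10.9 the plots. As a check of the code, 200 of the 37630 HEK293T peaks were removed and the others shortened. All 200 were found missing and 0 others were, an outcome that working code must give. On the deposited lists, the number of HEK293T peaks missing in KO equalled that from bedtools 2.31.1. A list of 30 genes with −800 bp added to each came out at percentile 0, and smaller shifts were not tried. Of 100 random lists without a planted change, 6 fell outside the central 95%.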

Results

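H3K9ac marks the promoters and enhancers of active genes. It was profiled by ChIP-seq in HEK293T cells, a human embryonic kidney line transformed with adenovirus DNA and expressing the SV40 large T antigen, in METTL3 knockout cells derived from them, and in the knockout complemented with wild-type or D395A METTL3. METTL3 is the catalytic subunit of the nuclear complex that writes N6-methyladenosine (m6A) on RNA, and METTL14 is its partner. The design asks whether H3K9ac depends on METTL3 and, through the D395A protein, on its catalytic activity; the series title names the acetyltransferase HAT1. Each kind of cell had 2 ChIP libraries and is represented by 1 peak list, so the comparisons below have no replicate spread.

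The list of HEK293T held 37630 peaks over 60.9 Mb, that of the KO 34057 over 55.4 Mb, that of the wild-type rescue 29762 over 50.3 Mb and that of the D395A rescue 31192 over 52.6 Mb. The HEK293T list held the largest part of weak peaks: 22.7% of its peaks had a −log10 q below 2, against 12.5% in the KO, 8.38% in the wild-type rescue and 8.92% in the D395A rescue. The number of strong peaks did not follow the length of the lists, with 14335 in HEK293T, 16673 in the KO, 16247 in the wild-type rescue and 17054 in the D395A rescue.

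METTL3, METTL14, HAT1 and the HAT1 partner RBBP7 had a peak at a gene end in all 4 lists. The METTL3 peak lay at chromosome 14, positions 21509929 to 21512907 in HEK293T and 21509957 to 21512822 in the KO, over one end of the gene. It covered 2979 bp of the window in HEK293T, 2866 bp in the KO, 2868 bp in the wild-type rescue and 2744 bp in the D395A rescue. Acetylation at this site does not report on a mutation in the coding sequence, so it is no check of the knockout. HAT1 had 3798 covered bp in HEK293T and 3233 in the KO, and RBBP7 had 6098 and 3888. All 22 genes of the m6A list and all 26 of the acetyltransferase list had a peak in every list, so no member of either differed in status.

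The first comparison asks which H3K9ac sites of HEK293T lack a peak in the KO and which sites of the KO lack one in HEK293T. Most genes were shared: 13701 genes had a peak at a gene end in HEK293T and 13525 in the KO, and 13147 had one in all 4 lists. A peak in HEK293T and none in the KO was found at 459 genes, 3.35% of the HEK293T genes, and the opposite at 283 genes, 2.09% of the KO genes. These were mostly weak sites of their list, with a median fold enrichment of 3.13 at the 459 genes against 13.5 at the genes with a peak in both. Which set was larger depended on the setting: with a −log10 q of at least 5 required in every list, 228 genes had a peak only in HEK293T and 355 only in the KO.

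Among the 10 genes with the highest HEK293T fold enrichment and no KO peak, MAGEA6 was the one with no covered base in the KO. It encodes a melanoma antigen family member whose expression in healthy tissue is largely limited to the germ line. Its HEK293T peak, at chromosome X, positions 152768539 to 152770926, lay over one end of the gene with a fold enrichment of 17.7. XKR5 had 1672 covered bp in HEK293T and 92 in the KO. At LOC128966722, BPIFC, CPT1B, SLURP1, SENP8, TOMT, MYBPC1 and NAALADL1, a KO peak lay outside the 1 kb window and within 5 kb, so the difference there is one of peak borders: CPT1B, a muscle carnitine palmitoyltransferase, had 4705 covered bp in HEK293T and 2321 in the KO.

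No KO base within 5 kb of either end was found at 263 of the 459 genes. The 15 of these with the highest fold enrichment, chosen after their values were seen, were MAGEA6, CDO1, CCDC170, MAGEA2B, MAGEA3, SPON1, RAB32, DECR1, FBXW9, PXDN, OSMR, CXCL1, HTR1F, RNF175 and OXCT1. CDO1, the dioxygenase that oxidises cysteine, had a HEK293T peak of fold enrichment 13.6 at chromosome 5, positions 115815777 to 115817247. OSMR, a receptor subunit for oncostatin M, had one of 10.1 at chromosome 5, positions 38845425 to 38846490, and the chemokine gene CXCL1 had one of 9.70 at chromosome 4, positions 73868910 to 73869834. RAB32, a small GTPase, and PXDN, an extracellular matrix peroxidase, had peaks of 11.8 and 10.7. None of the 15 had a peak in either rescue list. The MAGEA genes are near-identical copies, and reads may have been split between them, so their values are uncertain gene by gene.

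Of the 10 genes with the highest KO fold enrichment and no HEK293T peak, ZNF682 alone had no covered base in HEK293T. Its KO peak lay at chromosome 19, positions 20038673 to 20039552, with a fold enrichment of 23.5, and both rescue lists had a peak there. For the other 9, LOC124905344, IL17D, BHLHA9, BCAR1, EVC2, LOC124905565, PDE6G, SSBP4 and HSPB9, a HEK293T peak lay within 5 kb. At all of these but SSBP4 the KO peak overlapped a HEK293T peak, so the difference there is one of peak borders. SSBP4 had 3350 covered bp in HEK293T and 6723 in the KO. No HEK293T base within 5 kb was found at 153 of the 283 genes. The 15 loci of these with the highest fold enrichment, chosen after their values were seen, included ZNF682, ARHGAP6, NAAA, BHLHE22 with LOC124900252, ZNF492, ZNF66, ZNF737, ADAMTS12, COLEC10 with TNFRSF11B, CNTN5, PCDHA11, AEBP1, MUC8 and UNC5D. ARHGAP6 had a KO peak of fold enrichment 20.0 at chromosome X, positions 11664761 to 11666823. NAAA, a lysosomal hydrolase of fatty acid amides, had one of 17.6 at chromosome 4, positions 75939507 to 75941515. The neural transcription factor gene BHLHE22 had one of 16.1, and TNFRSF11B, which encodes osteoprotegerin, shared one of 10.3 with COLEC10. All 17 genes at these loci had a peak in both rescue lists.

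**Figure D1:**
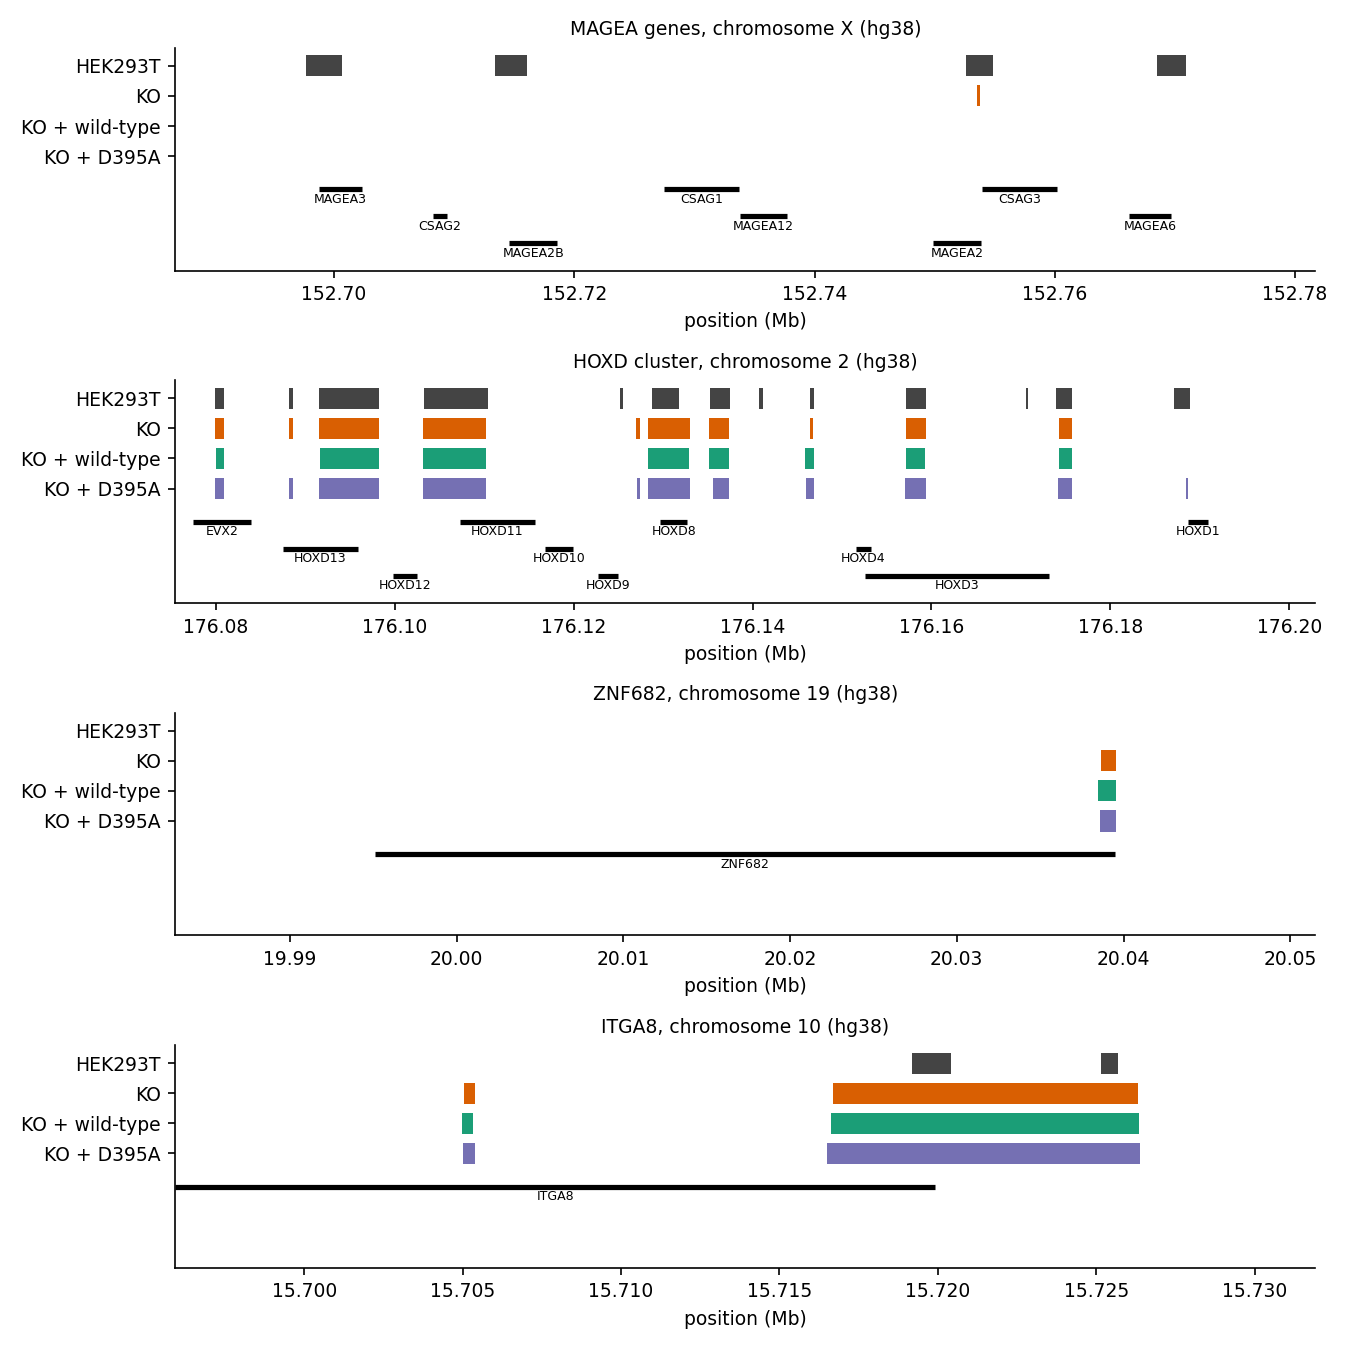
Maps of 4 regions in hg38, with position in Mb on the x axis, peaks of the 4 lists as coloured bars and annotated gene spans in black. The MAGEA region held 4 HEK293T peaks, 1 KO peak of 238 bp and 0 peaks in both rescue lists, while ZNF682 had peaks in the KO and both rescue lists and none in HEK293T, and around ITGA8 the peaks covered 1779 bp in HEK293T and 10000 bp in the KO.

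Among genes with a peak in both HEK293T and the KO, the number of bases covered by called peaks also differed. The width of a called peak can vary with depth and background, which are unknown here. Fewer covered bases therefore do not by themselves mean less or narrower acetylation. Of the 13147 genes with a peak in all 4 lists, 8855 had fewer covered bases in the KO than in HEK293T and 4265 had more, with a mean of 3440 bp in HEK293T and 3088 bp in the KO. The means of the wild-type and D395A rescues were lower still, 2948 and 3021 bp. Of 23976 regions of merged overlapping peaks present in all 4 lists, 54.3% were narrower in the KO than in HEK293T. The largest deficits in the KO were at CSK, the kinase that restrains SRC, with 9186 bp in HEK293T and 3750 bp in the KO, then at IBA57, C1QTNF6, PURB and IRAK1. PURB, a nucleic acid-binding protein, had 6898 and 2298 bp, and IRAK1, a kinase of Toll-like receptor signalling, had 7988 and 3512 bp. The largest surplus was at ITGA8, an integrin subunit needed for kidney formation, with 1234 bp in HEK293T and 8230 bp in the KO, where 1 KO peak spanned both HEK293T peaks, at chromosome 10, positions 15716693 to 15726324. CRIP2, DNAJB12, EEF1G and EIF3G followed. EEF1G, a translation elongation factor subunit, had 3496 and 8606 bp. At DNAJB12, EEF1G and EIF3G the counted window lay at the other gene end from the peak of highest fold enrichment. The surplus there is therefore no measure of the breadth of that peak. At EEF1G that peak lay at chromosome 11, positions 62568725 to 62575891 in HEK293T and 62570225 to 62576259 in the KO. Each rescue list lay nearer the KO than HEK293T at 9 of these 10 genes, for example at CSK, with 3484 bp in the wild-type and 3353 in the D395A rescue. The exceptions were DNAJB12, with 2653 bp in HEK293T, 7953 in the KO and 4704 in the wild-type rescue, and EIF3G, with 1755, 6494 and 3661 in the D395A rescue. Of the 2975 genes with a peak in all 4 lists and a difference of at least 1000 bp between HEK293T and the KO, a limit chosen after the data were seen, 12.3% (11.1 to 13.5) were nearer HEK293T in the wild-type rescue and 10.5% (9.40 to 11.6) in the D395A rescue. Without that limit, over 13120 genes, the shares were 25.5% (24.8 to 26.3) and 23.3% (22.6 to 24.1).

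Over the whole genome, 26685 of the 37630 HEK293T peaks were overlapped by a KO peak, 70.9% (95% Wilson interval 70.5 to 71.4), and 10945 were not. Of the KO peaks, 7391 (21.7%) were overlapped by no HEK293T peak. Shifted lists overlapped on average at 4.31% of HEK293T peaks. The missing share depended on strength: 71.3% of HEK293T peaks with a −log10 q below 2 had no KO peak, 44.0% of those from 2 to 5, 6.80% of those from 10 to 20, 2.82% of those from 20 to 50 and 0 of the 5316 at 100 or above. Missing peaks lay mostly away from gene ends. Of those on chromosomes 1 to 22 and X, 6.09% lay at the end of a protein-coding gene and 60.6% inside a gene body, while of the HEK293T peaks present in the KO 46.5% lay at a gene end; weighted to the strengths of the missing peaks, that share was 8.98%. The balance of both directions turned with the threshold: 1202 HEK293T peaks and 3889 KO peaks were unmatched when a −log10 q of at least 5 was required in every list, and 6066 and 6130 when lists of equal length were compared.

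**Figure D2:**
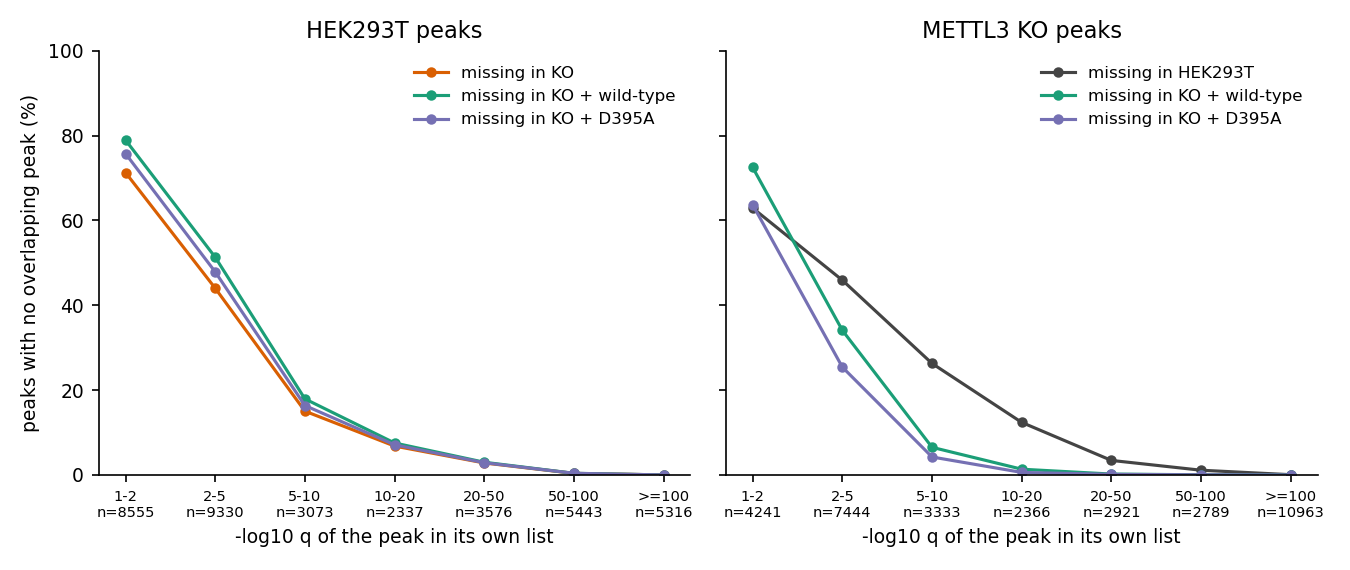
Percent of peaks with no overlapping peak in another list (y axis) against the −log10 q of the peak in its own list (x axis, bins with their number of peaks), for HEK293T peaks on the left and KO peaks on the right. Lines stand for the list searched; the share of HEK293T peaks missing in the KO runs from 71.3% in the weakest bin to 0 in the strongest.

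Strong peaks differed rarely. A −log10 q of at least 20 and no peak in the KO was found for 121 HEK293T peaks, 0.844% of 14335, and a strong KO peak without a HEK293T peak for 137, 0.822% of 16673. Of the 119 such HEK293T peaks on chromosomes 1 to 22 and X, 55 lay at gene ends (46.2%). Of 122 such KO peaks 30 did (24.6%). The shares were 74.8% of all strong HEK293T peaks and 68.8% of all strong KO peaks. The differing peaks were weaker and narrower than all strong peaks of their list. Their median width was 956 bp against 2648 bp in HEK293T, and 865 bp against 2185 bp in the KO. These shares were not weighted to strength, so they do not show whether differing strong sites avoid gene ends.

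The second comparison asks whether sites that differed in the KO returned with wild-type METTL3 and whether the D395A protein acted alike. Of the 459 genes with a peak in HEK293T and none in the KO, 426 (92.8%, 90.1 to 94.8) had none in either rescue list. A peak in the wild-type rescue only was found at 3 genes, in the D395A rescue only at 21, and in both at 9, so the wild-type count minus the D395A count was −18. The 3 were CYP2A7, SPACA3 and FMOD, with HEK293T fold enrichments of at most 3.34. The 10 of the 21 with the highest HEK293T fold enrichment were BPIFC, BRICD5, HOXD1, BCHE, ARSG, HOXC12, LOC110384692, DYNLRB2, SULT1C4 and DDT. Of these 10, 6 had covered bases in the KO as well, among them BPIFC with 2207 bp in HEK293T and 2776 in the KO, and at BPIFC, BRICD5 and HOXC12 the difference is one of peak borders. HOXD1, a homeobox gene, had 1790 covered bp in HEK293T, 0 in the KO and the wild-type rescue, and 238 in the D395A rescue. BCHE, the butyrylcholinesterase gene, had 1834 bp in HEK293T, 0 in the KO and the wild-type rescue, and 276 in the D395A rescue. Of the 263 genes with no KO base within 5 kb, 2 had a peak in the wild-type rescue only and 10 in the D395A rescue only. The wild-type rescue list was the shortest of the 4, which can move both counts. With lists of equal length they were 6 for the wild-type rescue only and 16 for the D395A rescue only, a difference of −10. With a −log10 q of at least 5 required in every list, the counts were 6 for the wild-type rescue only and 11 for the D395A rescue only.

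Genes that had a peak in the KO and none in HEK293T mostly had one in a rescue list. Of the 283, 160 (56.5%, 50.7 to 62.2) had a peak in both rescue lists and 73 in neither. A peak was absent from the wild-type rescue only at 35 genes and from the D395A rescue only at 15, a difference of 20. With a −log10 q of at least 5 required where a peak is present, it was 3, from 6 and 3 genes. The wild-type rescue list was the shortest, which can move these counts. It lacked 5867 of all KO peaks, against 4752 lacking in the D395A rescue. With lists of equal length the counts were 30 and 20 genes. Among the genes of the fixed lists, the 9 zinc finger genes with a peak in the KO and both rescues are given below, and CDH6, IFIT2, CHGB, NEUROD1 and ASGR1 had the same pattern.

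Peaks showed the same order as genes. Of the 10945 HEK293T peaks missing in the KO, 10038 (91.7%, 91.2 to 92.2) were missing in both rescue lists, 252 had a peak in the wild-type rescue only, 394 in the D395A rescue only and 261 in both. Of the 121 strong ones, 119 were missing in both rescue lists, 2 had a peak in the D395A rescue only and 0 had one in the wild-type rescue. Of the 7391 KO peaks missing in HEK293T, 3056 (41.3%) had a peak in both rescues, and of the 137 strong ones 131 (95.6%) did. All of these counts share the HEK293T list. Independent lists with these numbers of missing peaks would share 3605 peaks missing in both the KO and the wild-type rescue, or 7018 when drawn within bins of −log10 q, against 10432 observed; for strong peaks the values were 1.08, 3.10 and 121. Part of the excess may come from the shared HEK293T list, and with 1 list per kind of cell it could not be split.

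**Figure D3:**
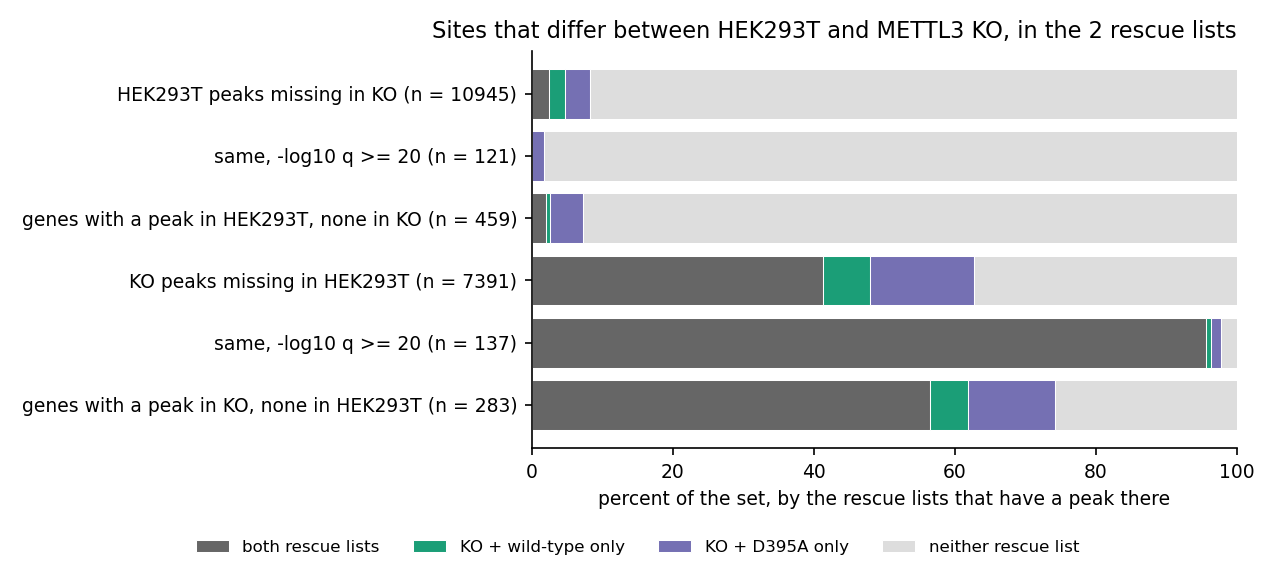
Stacked bars giving the percent (x axis) of each set of sites or genes that had a peak in both rescue lists, in 1 of them or in neither; the number in each set stands beside its bar. Of the 121 strong HEK293T peaks missing in the KO, 119 were in neither rescue list, and of the 137 strong KO peaks missing in HEK293T, 131 were in both.

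By covered bases, the lists from KO-derived cells resembled each other more than HEK293T. The Jaccard index was 0.636 between HEK293T and the KO, 0.641 between HEK293T and the wild-type rescue, and 0.645 between HEK293T and the D395A rescue. It was 0.806 between the KO and the wild-type rescue, 0.822 between the KO and the D395A rescue and 0.844 between the rescues. Of the wild-type rescue's peaks, 1436 (4.82%) had no KO peak, and 37.3% of those (34.8 to 39.8) had a HEK293T peak; for the D395A rescue the values were 1872 (6.00%) and 34.9% (32.8 to 37.1). Of the 16673 strong KO peaks, 7 were missing in the wild-type rescue and 5 in the D395A rescue.

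In 2 of the 26 gene lists, more genes had a HEK293T peak and no KO peak than in 97.5% of matched random lists; by chance up to 1.3 lists would lie outside the central 95%, both sides together. Of 28 pluripotency and germline genes 7 had a peak in HEK293T, and 3 of these, SALL4, MAGEA3 and MAGEA6, had none in the KO. Of matched random lists, 0.07% had as many. MAGEA3 and MAGEA6 are near-identical copies in 1 region, so they are not independent members, and the share counts each of them. SALL4, a stem cell transcription factor, had 3243 covered bp in HEK293T and 959 in the KO. Of 36 HOX genes with a HEK293T peak, HOXC12, HOXD9, HOXD3 and HOXD1 had none at a gene end in the KO, as many as in 1.90% of random lists. At HOXC12 and HOXD3 a KO peak outside the 1 kb window overlapped the HEK293T peak, so the difference there is one of peak borders; HOXC12 had 2396 covered bp in HEK293T and 797 in the KO, and HOXD3 had 2056 and 1447. At HOXD9 and HOXD1 no KO peak overlapped the HEK293T peak, which at HOXD9 was weak, with a −log10 q of 1.37. HOXD9 had 1618 covered bp in HEK293T and 2011 in the KO. Of 14 kidney and nephron genes, GATA3, SLC12A3, OSR1 and EYA1 had none in the KO (2.87% of random lists), and CDH6, a cadherin of the developing nephron, had a KO peak of fold enrichment 7.05 and none in HEK293T. OSR1 still had 1325 covered bp in the KO window against 1312 in HEK293T, GATA3 had 1184 against 2064, and EYA1 had 0 against 263. Of 27 epithelial-mesenchymal and cytoskeleton genes, EPCAM, COL3A1, MYL9 and SPARC had no KO peak (7.92%), and of 11 haematopoietic genes CD34, CD3E and KLF1 had none (20.7%), although KLF1 had 2095 covered bp in the KO and 3310 in HEK293T. SPARC, COL3A1, MYL9, CD34 and CD3E had 0 covered bp in the KO. In the neuronal and neural crest list 1 gene had a HEK293T peak and no KO peak. The random mean was 2.81, and 18.5% of random lists had as few. Matched on size only, the random mean was 0.71. These calls depend on the matching: with random lists matched on size only, 3.08% had as many as the HOX genes, against 0.14% for pluripotency and germline, 0.08% for kidney, 0.67% for haematopoietic and 1.27% for epithelial-mesenchymal genes. SLC12A3 was named after its values were seen. Of these 18 genes without a KO peak, HOXC12 and HOXD1 had one in the D395A rescue and none of the others had one in a rescue list.

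Zinc finger genes were the 1 list of 22 above its random lists in the opposite set, where up to 0.55 would be by chance. Of 114 genes named ZNF without a HEK293T peak, 11 had a KO peak. Random lists of genes without a HEK293T peak had a mean of 5.14, and 1.39% of them had as many. These random lists were not matched on strength and include families with few peaks. Olfactory receptors, for example, had 3 such genes against a random mean of 17.4. The 11 genes were ZNF682, ZNF737, ZNF66, ZNF492, ZNF880, ZNF528, ZNF347, ZNF525, ZNF556, ZNF648 and ZNF704, named in full after their values were seen. Of them, 9 lie on chromosome 19, and 9 had a peak in both rescue lists. ZNF880 and ZNF528 share 1 KO peak, which the 11 and the 1.39% count for each gene. Related copies can share reads, which leaves single zinc finger genes uncertain. In the other direction, 8 zinc finger genes had a peak in HEK293T and none in the KO, close to the random mean of 7.72; among them ZNF225 had a peak in both rescues, but its HEK293T peak overlapped a KO peak, so the difference there is one of peak borders. Of the protocadherin genes PCDHA11, PCDHB8 and PCDHGA1 had a peak in the KO and none in HEK293T (37.8% of random lists), as did the olfactory receptor genes OR51D1, OR52N2 and OR2G6.

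Covered bases around the gene, with the limit on their meaning given above, were compared as KO minus HEK293T. Over all 19974 genes, 9949 had fewer covered bases in the KO, 5291 had more and 4734 had the same number. HOX genes averaged 6639 bp in HEK293T and 7304 bp in the KO, a difference of 665 bp where matched random lists averaged −736 bp, and lay at percentile 100, with neighbouring HOX genes sharing peaks; 24 of 39 had more covered bases in the KO and 6 had fewer. Immediate early genes, which respond first to growth signals, differed by 164 bp against −485 bp in random lists (percentile 100.0), with 21 of 32 members more covered in the KO, among them CCN1 with 3669 bp in HEK293T and 6243 in the KO and NR4A1 with 3252 and 5478. In the wild-type and D395A rescues CCN1 had 5204 and 4516 bp and NR4A1 had 3656 and 4517. DUSP5 had 4150 and 1969 bp, and DUSP2, a phosphatase gene of the same list, had 1834 bp in HEK293T and 0 in the KO and both rescues. Targets of TGF-beta, Wnt, Notch and Hippo signalling differed by 31.1 bp (percentile 99.9): ID3 had 7044 bp in HEK293T and 10001, the whole window, in the KO, whereas HEY2 and AXIN2 had fewer in the KO and SP5, with no KO peak within 1 kb, had 2190 and 1243. Replication-dependent histone genes differed by −185 bp (percentile 99.6), with H2BC9 and H3C7 sharing a HEK293T peak without a KO peak within 1 kb (2085 covered bp in HEK293T and 629 in the KO) and H1-2 and H4C7 less covered. Chromatin remodellers and Polycomb or Trithorax genes differed by −290 bp (percentile 99.2). Among them KDM6B, a histone demethylase, had 4151 bp in HEK293T and 8370 in the KO, SUZ12 and KMT2A had fewer in the KO, and SETD1B, with no KO peak within 1 kb, had 3210 bp in HEK293T and 2846 in the KO.

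Pluripotency and germline genes (−321 bp, percentile 0.01) and olfactory receptors (10.3 bp, percentile 0.05) lay below their random lists. Of the pluripotency and germline genes, 7 had fewer covered bases in the KO, 6 had more and 15 had the same number, with the largest deficits at MAGEA3, MAGEA6 and SALL4. Their median difference was 0 bp, and MAGEA3 and MAGEA6 are near-identical copies in 1 region. Of the olfactory receptors, 5 had fewer and 16 had more. These 7 lists compare with 1.3 of 26 expected outside the central 95% by chance; HOX and immediate early genes alone stayed outside on the same side when random lists were matched on size only, and olfactory receptors moved to the opposite side.

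Most other groups had fewer covered bases in the KO. Unfolded protein and heat shock genes differed by −974 bp (percentile 6.20), with ERN1, HSPA5 and DNAJC3 less covered and HSPA1B more. DNA replication genes differed by −812 bp (percentile 11.1), where GINS2 had 5975 bp in HEK293T and 2204 in the KO, with RRM2, MCM5 and POLE also less covered. DNA repair genes differed by −711 bp (percentile 8.25; XRCC5, CHEK2, XRCC6 and ATM), ribosomal protein genes by −706 bp (percentile 72.6; RPL37A, RPS9, RPL14 and RPS28) and cholesterol and fatty acid genes by −670 bp (percentile 16.7; SCD, SC5D, LSS and MVK). Acetyltransferase genes differed by −634 bp (percentile 31.5), with RBBP7, TADA2B, KAT5 and CLOCK less covered. The m6A genes differed by −612 bp (percentile 57.1), with VIRMA, YTHDC1 and CBLL1 less covered and RBM15B more, with 2763 bp in HEK293T, 4045 in the KO, 2689 in the wild-type rescue and 2753 in the D395A rescue. Proteasome genes differed by −436 bp (percentile 34.9; PSMA3, PSMA1, PSMA2 and PSMD9) and respiratory chain genes by −356 bp (percentile 73.8), where NDUFA7 and ATP5IF1 were less covered, ATP5F1D more, and NDUFA5, with a peak within 1 kb in the KO list only, had 2445 bp in HEK293T, 3825 in the KO, 2511 in the wild-type rescue and 2486 in the D395A rescue. At NDUFA5 the KO peak overlapped a HEK293T peak, so the difference in status is one of peak borders. NDUFA7 shares its peak with its neighbour RPS28 of the ribosomal protein list. Deacetylase genes differed by −275 bp (percentile 84.3), with HDAC3, HDAC11 and SIRT7 less covered and RCOR2 more.

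The remaining groups had smaller mean differences. Epithelial-mesenchymal genes differed by −159 bp (percentile 69.8), zinc finger genes by −128 bp (percentile 68.9), p53 targets by −113 bp (percentile 95.8), haematopoietic genes by −53.8 bp (percentile 38.3), hepatocyte genes by −36.2 bp (percentile 29.8) and neuronal genes by −11.7 bp (percentile 85.3). Protocadherin genes differed by 71.7 bp (percentile 68.0), kidney genes by 105 bp (percentile 97.49) and interferon genes by 124 bp (percentile 94.8). Among the p53 targets SESN2 and PLK3 had fewer covered bases in the KO and PMAIP1 and TP53INP1 more. Of the interferon genes IFITM1 and IFITM3 had more, IFIT2 had a KO peak and none in HEK293T, and OASL had a HEK293T peak and no KO peak within 1 kb, with 1450 and 1392 covered bp. Of the neuronal genes INA had a peak in HEK293T alone, CHGB and NEUROD1 had one in the 3 other lists (NEUROD1 with 795 covered bp in HEK293T and 637 in the KO), and HAND1 had fewer covered bases in the KO. ASGR1 was the one hepatocyte gene with a KO peak and no HEK293T peak within 1 kb, although it had 1493 covered bp in HEK293T and 1606 in the KO. The KO peak at ASGR1 overlapped a HEK293T peak, so the difference there is one of peak borders. Few of these peaks were present in a rescue: of the 33 list members with a HEK293T peak and no KO peak, counting a gene once per list, 1 (ZNF225) had a peak in the wild-type rescue and 3 in the D395A rescue, beside 12 and 30 of all 459 such genes.

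Between the rescues, 4 of the 26 lists lay above their random lists for covered bases, wild-type minus D395A, and 0 below, where 1.3 would lie outside by chance. Histone genes differed by 47.5 bp against −102 bp in random lists (percentile 99.85), protocadherin genes by 16.8 bp against −16.4 bp (98.88), acetyltransferase genes by 81.2 bp against −81.8 bp (98.43) and zinc finger genes by −27.0 bp against −50.5 bp (98.05). For the wild-type rescue minus the KO, 2 lists lay above, histone genes (−10.9 bp, percentile 100) and zinc finger genes (−53.0 bp, 99.04), and for the D395A rescue minus the KO 2 did, HOX genes (30.7 bp, 99.79) and signalling targets (45.3 bp, 98.32).

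**Figure D4:**
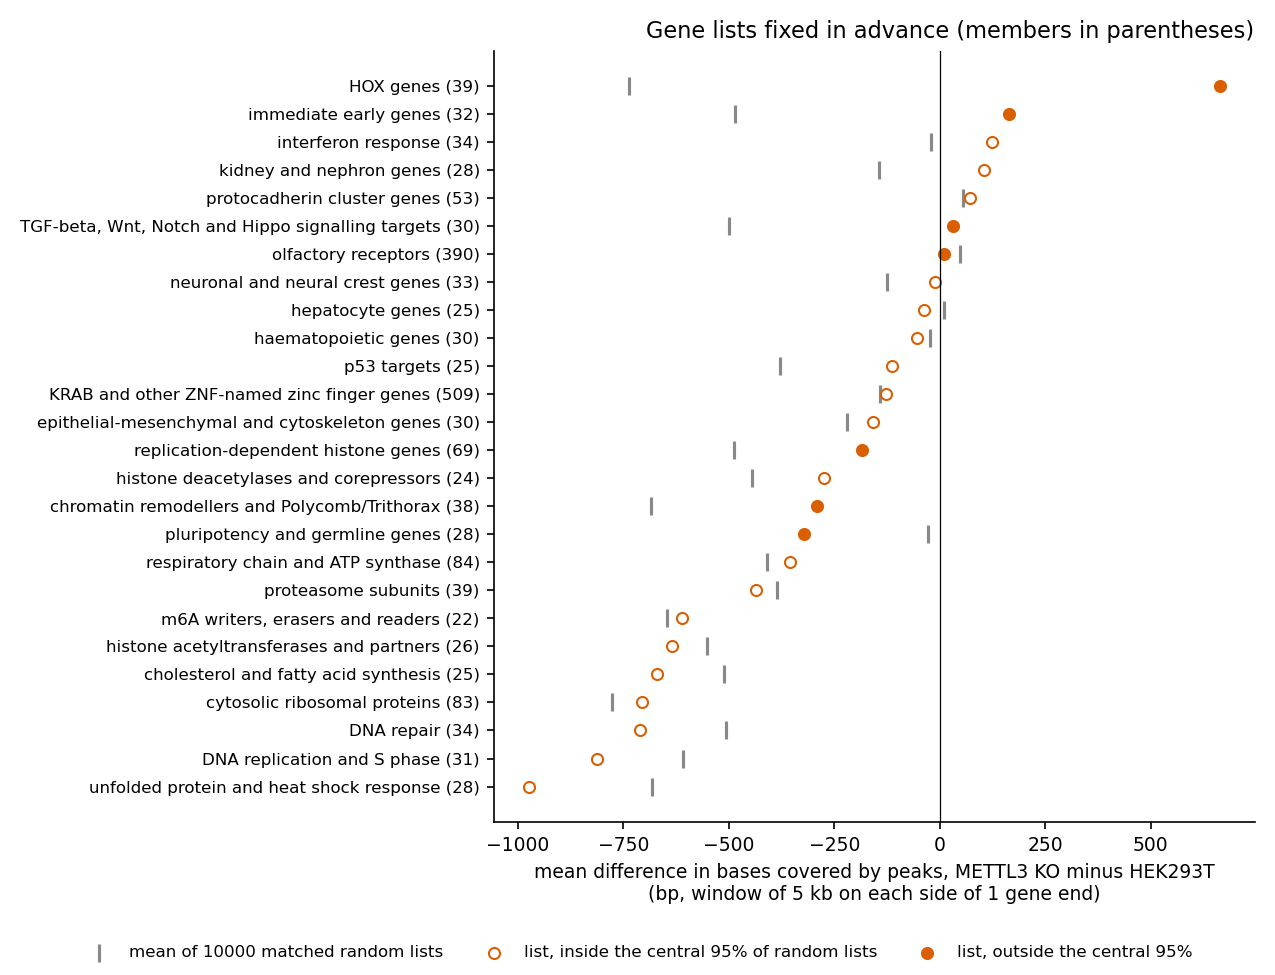
Mean difference in bases covered by peaks, KO minus HEK293T (x axis, bp), for the 26 gene lists (y axis, members in parentheses), with the mean of 10000 matched random lists as a grey tick. Filled points lie outside the central 95% of random lists; HOX genes lie at 665 bp and unfolded protein and heat shock genes at −974 bp.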

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

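No paired analysis was possible because each kind of cell has 1 peak list and no list carries a replicate; for the same reason no replicate could be left out. Absence within 5000 bp and the limit of −log10 q 20 were chosen after seeing the data. Of 47 alternative values, 29 stayed close and 18 moved further. The 29 include the gene values under the restriction to numbered chromosomes and X. Those gene values could not move, because all genes used already lay on these chromosomes. Most of the 47 values are counts, which have no sign. Both rescue differences kept their sign. Close means within 1.5 times for counts and, for both rescue differences, a share of genes from each rescue inside the exact 95% interval of the reported share, so that the size of the difference can still move. With a −log10 q of at least 5 in every list, 1202 HEK293T peaks were missing in the KO and 3889 KO peaks in HEK293T, 228 genes had a peak in HEK293T and none in the KO, and the wild-type minus D395A difference over such genes was −5. With that limit only where a peak is present, the values were 742 and 1306 peaks, 177 genes and 143 in the opposite direction, and a difference of −4. Lists of equal length left 6066 HEK293T peaks missing in the KO and a difference of −10. The same difference was −8 with windows of 2500 bp and −9 with 1 end per gene. No peak within 5000 bp was found for 7091 HEK293T peaks, and no base within 5000 bp of a gene end at 263 and 153 genes. At a −log10 q of at least 20, 121 and 137 peaks remained. The cause of these shifts was not tested. Random lists matched on size only placed 14 gene lists outside the central 95% in place of 7. With that matching pluripotency and germline genes lay at percentile 27.2, replication-dependent histone genes at 70.9, chromatin remodellers at 32.9, signalling targets at 97.5 and olfactory receptors at 100. The difference among genes with a KO peak and none in HEK293T stayed above 0 under every alternative run for it, but was 3 with a −log10 q of at least 5 where a peak is present, 10 at equal list length and 32 with windows of 2500 bp, against 20 as reported. Depth is unknown, so how far weak peaks reflect sequencing depth was not measured.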

Other observations

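The tests of threshold noise, uniform sensitivity, restoration by wild-type METTL3, gene-rich chromosomes, weak peaks on chromosome 22 and a lost MAGEA segment were chosen after the result was seen; those of lost segments and of chromosome 22 copies were written before. The genes and regions in the next paragraph were also chosen after their values were seen.

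The MAGE genes on chromosome X split in 2 directions. MAGEA1, a further member of the MAGEA family, had a HEK293T peak of fold enrichment 9.08 and none in the KO or the rescues. MAGEA2 had one of 10.4 in HEK293T and a KO peak of 3.43, with none in the rescues. MAGEB2, another germline antigen gene of the X chromosome, had a peak in the KO and both rescues and none in HEK293T. The HOX clusters also differed among themselves. Peaks covered 87.9 kb of the HOXA cluster in HEK293T, 98.5 kb in the KO, 96.4 kb in the wild-type rescue and 97.5 kb in the D395A rescue, in 8, 4, 3 and 4 peaks, so that fewer and longer peaks filled the cluster. In the HOXB cluster the covered length was 78.3 kb in HEK293T and 85.6 kb in the KO. In the HOXC cluster it was 82.3 and 80.9 kb, although the mean around its gene ends was 6928 bp in HEK293T and 7908 bp in the KO, and in the HOXD cluster, which holds 3 of the 4 HOX genes with a HEK293T peak and no KO peak within 1 kb of a gene end, 26.8 and 25.7 kb, with means of 3403 and 3358 bp around gene ends.

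Weak HEK293T peaks made up most of those missing in the KO and both rescues. The share missing in the KO was 0.844% at a −log10 q of 20 and above against 71.3% below 2. Threshold noise, peaks near the caller's limit that come and go, predicts such a fall, but the fall is the pattern itself and does not test it. A high missing share of the weakest peaks was not particular to HEK293T. Of KO peaks below 2, 72.5% had no peak in the wild-type rescue, 63.7% none in the D395A rescue and 62.9% none in HEK293T. From 2 to 5 the shares were 34.1%, 25.4% and 45.9%. Of the wild-type rescue's peaks below 2, 31.2% had no KO peak. Threshold noise and a METTL3 effect limited to weak sites both stay open and untested.

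Of the 121 strong HEK293T peaks missing in the KO, 119 were missing in both rescues as well. A uniformly lower sensitivity of the KO-derived lists is argued against by the values between: 2.82% of HEK293T peaks with a −log10 q from 20 to 50 were missing in the KO although 20 peaks at 50 or above were. Lost chromosome segments that hold more than 1 strong peak would remove strong neighbours together, whereas a lost segment with 1 strong peak would go unseen here. Over the whole genome, only 1.68% of the strong missing peaks (2 of 119, interval 0.462 to 5.92) stood next to another one. The pair lay at MAGEA3 and MAGEA2B, where 1 weak KO peak of 238 bp remained between MAGEA3 and MAGEA6, so a lost segment with the MAGEA genes stays open. Of these peaks 0% had one in the wild-type rescue list (0 of 121, upper limit 3.08), which restates the pattern and does not test whether the catalytic activity of METTL3 is involved. What the 3 KO-derived lists share and HEK293T lacks stays open and untested, which could be the derivation of the KO cells, a library batch, the input used as control, or an effect of METTL3 loss that complementation did not undo.

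Chromosome 22 had the highest share of HEK293T peaks missing in the KO, 42.3% (39.5 to 45.1) against a median chromosome of 29.3%, and 50.2% were missing in the wild-type rescue. Chromosome 15 followed with 37.0% (34.5 to 39.6) missing in the KO. Gene density alone does not account for the share of chromosome 22: of the 4 chromosomes with more genes per Mb, chromosome 17 had the highest share, 31.8% (29.9 to 33.7), and chromosome 19, the densest, had 22.7% (21.0 to 24.5). Weak peaks were more frequent on chromosome 22 than elsewhere, and the strengths of its peaks predict a share of 38.2%, which covers most of the excess and lies below the interval of the observed share. Fewer copies of chromosome 22 in the KO cells would affect its whole length. All 5 consecutive parts, each of 246 of its peaks, had intervals above the median chromosome. The weak peaks would spread the excess in the same way, so the parts cannot tell a copy difference from them. Whether copy number also affects the strengths of the HEK293T peaks is unknown here, so the predicted share does not bound its part. A copy difference remains a candidate explanation, and no copy numbers were measured. Among peaks with a −log10 q of at least 5 the missing share was 4.06% on chromosome 22, 4.95% on chromosome 15, 4.38% on chromosome X and 3.90% over chromosomes 1 to 22 and X.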
